A study of Homo sapiens with 6 samples.

How the data were processed

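Bulk RNA-seq of WTC11 cardiac progenitor cells was used, 6 libraries in 2 groups of 3, and the group of each library was read from the labels. Per the labels' protocols, total RNA was isolated with 500 ng taken into a stranded total RNA kit. The cells had been frozen at day 5 and were collected at day 6. Per the submitters' processing notes, reads were aligned with STAR 2.5.3a to hg38 and counted per gene with featureCounts 2.0.3. The annotation and the strand setting of the counting are not given in the sources used here. The deposited counts are whole numbers per gene summed over its exons, in 43388 rows, of which 11587 are at 0 in every library. The Length values, exonic bases per gene, came with the deposited count table per the file headers. The deposited TPM values equal counts divided by that length and rescaled per library, with a largest difference of 4.7e-05; how the authors made them is not given in the sources used here. Among the TPM rows, 27 gene names had been turned into dates, and these were matched by row order to the count table.

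The main tests used the counts. Genes were filtered with filterByExpr by group, which left 17201 genes holding at least 99.75% of the counts of each library. edgeR 4.0.16 in R 4.3.3 was used with TMM normalisation, a robust quasi-likelihood fit with group as the only term, and the Benjamini-Hochberg adjustment. A gene was called at an adjusted p below 0.05, and a second count kept calls with an absolute log2 fold change of at least 1. The biological coefficient of variation was 6.3%. In counts simulated on these libraries with 200 changed genes, edgeR recovered 54.5% of 1.5-fold, 80% of 2-fold and 100% of 4-fold changes, with 0.07% false calls among unchanged genes. The data gave 7085 calls, and the adjusted cutoff depends on how many genes differ, so these rates do not carry over to the real comparison. For a gene with no count in a group, the fold is a bound against a floor of 3 counts over the group.

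Gene lists were written from textbook knowledge before the data were examined: 38 in all, of which 36 had the 5 measured members needed. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry as alternatives; 22 were called, 12 higher and 10 lower. Counts of members are given over all genes tested and adjusted over the list alone. The genes named were set by a rule: the 12 highest and the 12 lowest log2 fold changes among called genes with a mean CPM of at least 5 and no overlap between groups. To these were added up to 4 called members of each list with the largest absolute log2 fold change and a mean CPM of at least 1, and a fixed panel of cardiac and early lineage genes. Not every member that the rule names is reported here. Clone-type names, non-coding families, pseudogenes and sex-linked markers were outside the rule for extremes.

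Library composition was compared with an exact permutation test of the difference of means, whose smallest p for 3 against 3 is 0.1. Similarity used 15972 genes with a mean CPM of at least 1. A chi-square comparison of raw counts found no pair of duplicated libraries, with 2.05 to 11.63 per degree of freedom within groups. Exonic overlap came from the exon coordinates in the deposited count table, and copies on other sequences from its row names. Gene type came from a RefSeq table and GC content from GENCODE 29 transcripts. A gene with over 10% of its exonic bases opposite another gene is named as such. Depth was 12102107 to 17894689 assigned counts per library.

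Alternatives tried were other normalisations (RLE, upper quartile, library totals), no filter and a stricter filter (CPM of at least 5 in 3 libraries), DESeq2 1.42.0, limma-voom, glmTreat against a 1.5-fold minimum, limma on log2 TPM, a block on the replicate number of the titles, corrections for gene length, removal of mitochondrial, ribosomal, RN7S and histone genes, and each library left out. A correction for GC content and length was added after the results were seen, with GC content for 86.6% of tested genes. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9. Raw reads were not analysed here.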

Results

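The expression data came from cardiac progenitor cells made from WTC11, an established human induced pluripotent stem cell line. Cells were taken through a cardiac differentiation in which WNT signalling is first switched on with a GSK3 inhibitor and then blocked with IWP2 from day 2. Progenitors were pooled and frozen at day 5, then thawed, plated overnight and collected at day 6. The labels divide 6 RNA-seq libraries into 3 from high-efficiency progenitors, whose batches later gave a high purity of cardiomyocytes, and 3 from low-efficiency progenitors, whose batches gave a low purity. Total assigned counts were 14063697, 14894054 and 12102107 in the high libraries and 17894689, 12824010 and 12871035 in the low libraries. Between 25432 and 26506 genes had at least 1 count in a library. Log2 fold changes below are high over low, levels are CPM (counts scaled to the normalised library size) as mean ± SD with n = 3 per group, and coordinates are on hg38.

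The comparison asks which transcripts at the progenitor stage go with the later purity of cardiomyocytes. High-efficiency progenitors had more RNA of all 19 measured endoderm genes and of 14 of 16 epithelial genes, the keratins KRT8 and KRT18 going the other way. Among those higher were HHEX at 69.1 ± 0.811 CPM against 7.14 ± 1.10 and CDH1 at 105 ± 3.65 against 21.7 ± 1.20. Among the cardiac progenitor factors they had more NKX2-5, ISL1 and MEF2C, and less TBX5 and HAND1. Low-efficiency progenitors had more RNA of all 7 anterior and of 6 of 7 central and posterior HOX genes measured, HOXA13 going the other way. They also had more of the epicardial factors WT1, TBX18 and BNC2, of 17 of 23 listed fibroblast and matrix genes and of 20 of 22 cholesterol synthesis genes. COL3A1, a fibrillar collagen of loose connective tissue, stood at 1969 ± 47.5 CPM in the low libraries and 248 ± 15.1 in the high libraries. Of the 36 lists tested only 1, the endoderm list, stayed called when camera estimated the correlation per list.

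Of 17201 genes tested, 7085 differed at an edgeR adjusted p below 0.05, with 3518 higher and 3567 lower in the high libraries. At least a 2-fold difference was seen for 1945 of these, 1020 higher and 925 lower. In 49.4% of the tested genes the groups did not overlap, where chance gives 10% for 3 libraries against 3. The libraries of a group were alike: Pearson correlations across genes were 0.9947 to 0.9952 within high, 0.9924 to 0.9935 within low and 0.9636 to 0.9648 between groups. The first principal component held 79.7% of the variance and separated the groups. With library totals as the only scaling, 59.4% of the calls were higher, against 49.7%. The labels give all high libraries one description prefix and all low libraries another, without saying what it marks, so the prefix and the group cannot be told apart. The titles call the libraries biological replicates, but nothing states that those of a group came from separate differentiations, and wells were pooled before freezing, so p-values measure only the spread between these samples, which may be technical.

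**Figure D1:**
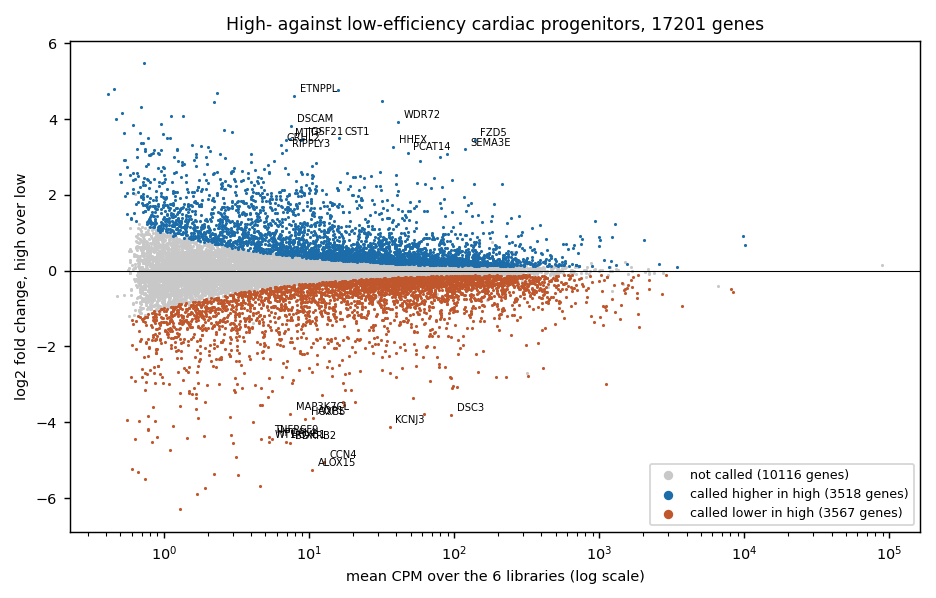
Log2 fold change of each tested gene (high over low) against its mean CPM over the 6 libraries on a log scale, with called genes coloured and the genes named by the rule for extremes labelled. Genes with a group at 0 are drawn at the bound that 3 counts over the group allow, and the 3518 higher and 3567 lower calls spread on both sides of 0 at all levels.

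The highest ranked gene by the fixed rule was ETNPPL (chromosome 4, 108742040 to 108763079), a phospholyase of phosphoethanolamine, at 15.2 ± 0.258 CPM in the high libraries and 0.601 ± 0.0668 in the low, a log2 fold change of 4.62 (SE 0.22, edgeR adjusted p = 1.87e-21). FZD5, a WNT receptor (chromosome 2), rose by 3.46 to 254 ± 13.9 CPM from 23.1 ± 1.86. SEMA3E, a secreted guidance cue, was at 215 ± 5.47 CPM against 23.6 ± 2.28. MTTP, which loads lipid onto apolipoprotein B, differed by 3.47, and GRHL2, a transcription factor of epithelia, by 3.32. The other genes at this end were WDR72, DSCAM, IGSF21, HHEX, RIPPLY3, PCAT14 and CST1, between 3.10 and 3.93. CST1 has close paralogs, so its counts are uncertain, as are those of WDR72 and FZD5, which share 12% and 16% of their exonic bases with genes on the opposite strand.

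At the other end, ALOX15 (chromosome 17), a lipoxygenase, was at 0.530 ± 0.220 CPM in the high and 20.5 ± 1.98 in the low libraries, a log2 fold change of -5.26 (SE 0.22, edgeR adjusted p = 2.16e-23). CCN4, a matricellular protein and known WNT target, differed by -5.04. DSC3, a desmosomal cadherin, fell by 3.81 to 12.7 ± 0.962 CPM from 178 ± 4.41. KCNJ3, a subunit of the atrial acetylcholine-gated potassium channel, was at 3.92 ± 0.393 CPM against 68.1 ± 3.01. WT1, HOXB1, HOXB5, AQP1, BDKRB2, HPCAL4, TNFRSF9 and MAP3K7CL made up the rest, between -4.54 and -3.78.

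Cardiac genes did not move as a block. Among 21 measured cardiac progenitor transcription factors, 13 were higher in the high libraries, 5 lower and 3 not called. NKX2-5 was at 14.3 ± 1.02 CPM against 6.38 ± 1.05 (log2 fold change 1.19, SE 0.14, edgeR adjusted p = 4.12e-09), ISL1 at 54.7 ± 2.07 against 24.1 ± 1.45, MEF2C at 220 ± 7.18 against 90.3 ± 3.42, and TBX3, a factor of the conduction system, at 125 ± 1.90 against 36.0 ± 1.47. GATA4 and TBX20 rose by 0.30 and 0.57. HAND1, which marks the first heart field and extraembryonic mesoderm, was at 36.6 ± 1.39 CPM against 112 ± 2.04. TBX5 differed by -0.88. HEY1 and ZFPM2 were also lower, the latter chosen after its values were seen. The list as a whole was called higher (camera adjusted p = 0.0371, median 0.30), but adjusted p = 0.208 with an estimated correlation. The camera call was also lost without high replicate 2 (adjusted p = 0.0504) and with a stricter count filter (adjusted p = 0.0560).

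Of 29 contractile and calcium-handling genes, 19 rose, 3 fell and 7 were not called (median 0.27, camera adjusted p = 0.000192; adjusted p = 0.1 with an estimated correlation). MYH6, the atrial myosin heavy chain, stood at 1300 ± 69.9 CPM against 698 ± 69.0, ACTN2 at 150 ± 2.46 against 90.4 ± 1.71, and MYOM1 and UNC45B differed by 0.74 and 0.97. ACTC1 differed by -0.10 at 2800 ± 95.9 against 3007 ± 87.1 CPM (edgeR adjusted p = 0.0413), a call lost under 11 of 21 alternatives. These were 4 of the 6 left-out libraries, upper-quartile and library-total scaling, no filter, glmTreat and the 3 fits on log2 TPM, and over all 21 the value of ACTC1 lay between -0.14 and -0.04. TPM1 was also lower and was chosen after its values were seen. TNNT2, the usual marker for cardiomyocyte purity, did not pass the test: 378 ± 36.6 CPM against 509 ± 104, log2 fold change -0.43 with a 95% interval of -0.92 to 0.07. TNNT2 passed without low replicate 2, at -0.26, and with limma on log2 TPM under all 3 settings, at -0.37. It also passed with a block on the replicate number of the titles. KDR and PDGFRA, surface markers used to sort cardiac mesoderm, were 0.46 and 0.27 higher. For the progenitor factor list and the contractile list the counts adjusted over the list alone were the same. In the same libraries the endoderm list had a median of 2.12 and the epicardial list of -1.73.

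**Figure D2:**
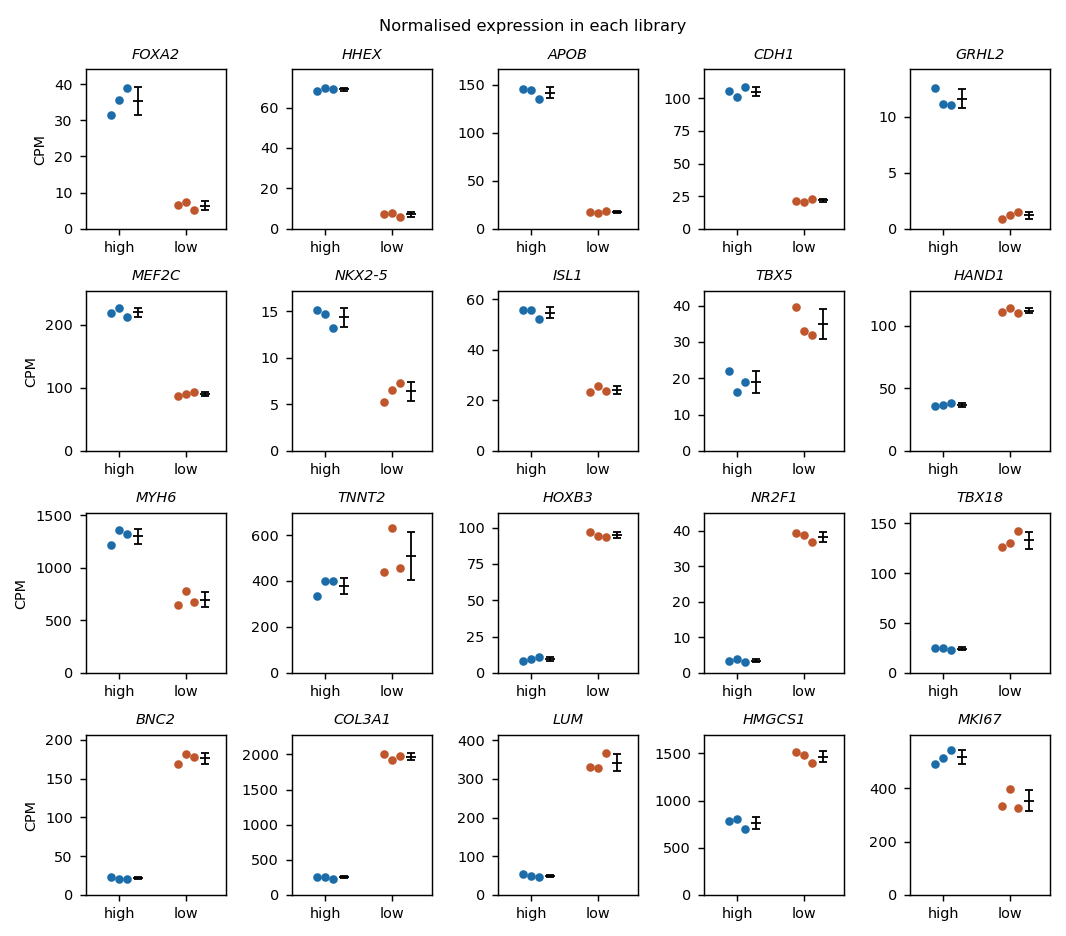
CPM on a linear scale from 0 in each of the 3 high and 3 low libraries (points), with the mean and SD of each group beside them, for 20 genes of the fixed lists. The groups do not overlap for any of the 20, though TNNT2 did not pass the test.

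All 19 measured genes of the endoderm and gut list were higher in the high libraries, 17 of them by at least 2-fold, with a median difference of 4.36-fold (camera adjusted p = 3.04e-16; adjusted p = 0.0349 with an estimated correlation). It was the only list of 36 still called with an estimated correlation. FOXA2, a pioneer factor of endoderm, was at 35.3 ± 3.80 CPM against 6.39 ± 1.20 (log2 fold change 2.46, SE 0.12, edgeR adjusted p = 2.36e-20). APOB, the core protein of lipoproteins, was at 142 ± 5.48 against 17.6 ± 1.42, and TTR at 158 ± 4.21 against 19.2 ± 4.56. SOX17 differed less, at 6.29 ± 1.38 CPM against 3.59 ± 0.776. Of 16 epithelial genes, 14 rose and 2 fell, with a median of 2.06 (camera adjusted p = 9.5e-09; adjusted p = 0.1 with an estimated correlation). EPCAM, shared by both lists, was at 226 ± 16.4 CPM against 46.6 ± 4.65 and ESRP1, an epithelial splicing factor, at 67.1 ± 1.16 against 11.8 ± 1.14. KRT8 and KRT18, a keratin pair also made in cardiac progenitors, were the 2 that fell, by 0.50 and 0.45, and were chosen after their values were seen. Both lists kept these counts when adjusted over the list alone.

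HOX genes gave the largest median differences of any list. All 7 measured anterior HOX genes were lower in the high libraries (median 8.92-fold lower, camera adjusted p = 1.08e-07; adjusted p = 0.0657 with an estimated correlation). HOXB3 was at 9.35 ± 1.44 CPM against 94.8 ± 2.16, HOXB4 at 3.56 ± 0.463 against 32.0 ± 1.35 and HOXB1 at 0.572 ± 0.0912 against 13.3 ± 2.16. Of 7 central and posterior HOX genes 6 were lower, including HOXB5, HOXB6, HOXB7 and HOXC8, and HOXA13, chosen after its values were seen, was 1.28 higher (list median -4.19, camera adjusted p = 0.000139; adjusted p = 0.0956 with an estimated correlation). In the HOXB cluster on chromosome 17, all 9 genes from HOXB1 (start 48528526) to HOXB9 (end 48626358) were lower, a stretch chosen after its values were seen. The HOX counts were the same when adjusted over the list alone. HOXA3 shares 12.7% of its exonic bases with antisense genes.

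**Figure D3:**
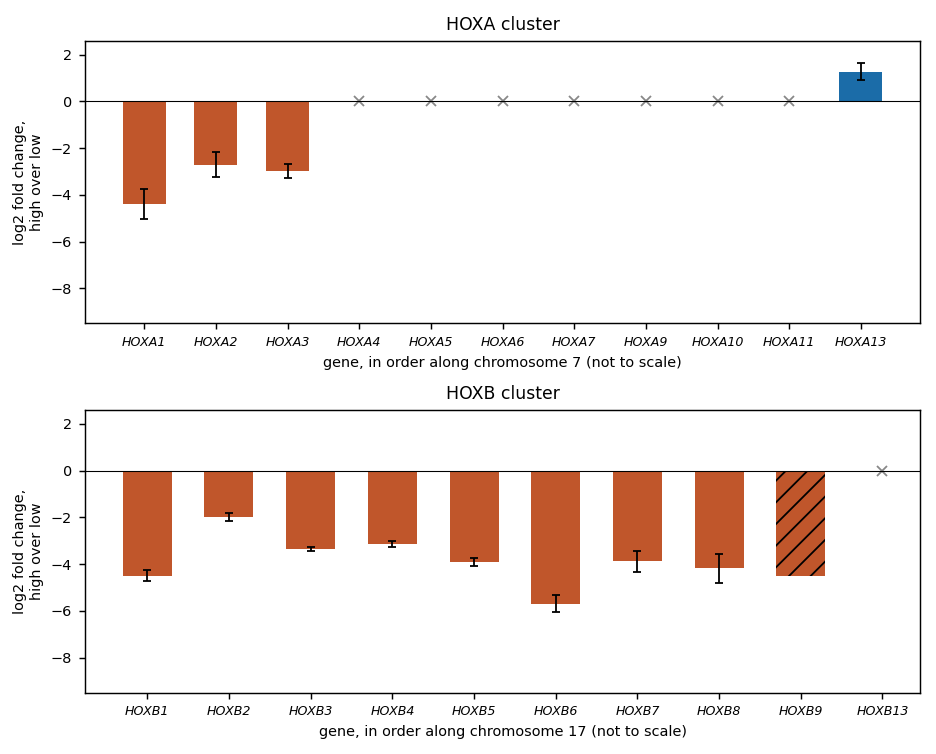
Log2 fold change (high over low) with its SE for the HOXA genes on chromosome 7 and the HOXB genes on chromosome 17, in chromosomal order and not to scale. Crosses mark genes with too few counts to test; the hatched bar is HOXB9, at 0 in every high library and drawn at the bound of 3 counts over the group.

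Of 11 epicardial genes 6 were lower, 2 higher and 3 not called (median -1.73, camera adjusted p = 0.00785; adjusted p = 0.106 with an estimated correlation). BNC2 was at 21.5 ± 1.44 CPM against 176 ± 6.60, TBX18 at 24.2 ± 1.51 against 133 ± 8.31, WT1 (chromosome 11) at 0.419 ± 0.178 against 10.1 ± 2.31 and ALDH1A2, the embryonic retinoic acid synthase, at 0.470 ± 0.235 against 1.77 ± 0.711. The higher members were SEMA3D and KRT19, chosen after their values were seen. Of 23 fibroblast and matrix genes, 17 fell, 4 rose and 2 were not called, with a median 2.12-fold lower (camera adjusted p = 9.63e-11; adjusted p = 0.0657 with an estimated correlation). LUM, a small proteoglycan of collagen fibrils, was at 49.0 ± 3.18 CPM against 342 ± 21.0 and COL6A3 at 22.5 ± 2.11 against 188 ± 3.92, while DCN was at 0.147 ± 0.129 against 6.36 ± 0.512. FN1, VCAN and FBN2, chosen after their values were seen, rose by 0.90, 0.80 and 0.16, with PDGFRA as the other higher member. Of 12 smooth muscle genes 9 fell and 1, RGS5, rose (median -0.80, camera adjusted p = 1.02e-06; adjusted p = 0.1 with an estimated correlation). CALD1 was at 809 ± 5.56 CPM against 1957 ± 150 and CNN1 at 124 ± 1.17 against 281 ± 24.9. RGS5 was chosen after its values were seen. These 3 lists had the same counts when adjusted over the list alone.

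All 24 measured genes of G2 and M phase rose, by 0.19 to 0.67, none by 2-fold (median 0.43, camera adjusted p = 3.3e-11; adjusted p = 0.1 with an estimated correlation). MKI67 was at 517 ± 25.2 CPM against 353 ± 39.5 and CCNB2, a mitotic cyclin, at 69.3 ± 1.55 against 44.0 ± 0.751. Of 24 S phase genes 10 rose, 1 fell and 13 were not called (camera adjusted p = 0.0373; adjusted p = 0.464 with an estimated correlation). CCNE1, which drives entry into S phase, was at 12.0 ± 0.624 CPM against 5.15 ± 1.28, and SLBP, which binds the histone message, was the member that fell. The S phase call by camera was lost without high replicate 2, low replicate 1 or low replicate 3, at adjusted p = 0.0569, 0.0914 and 0.0580, and with the stricter count filter, at adjusted p = 0.0521. Of 35 replication-dependent histone genes 19 rose and 16 were not called, or 21 rose when adjusted over the list alone (median 0.50, camera adjusted p = 5.21e-06; adjusted p = 0.441 with an estimated correlation). HIST1H4A and HIST1H2BM rose most, by 1.19 and 1.13. Adjusted over the list alone, the other counts were the same.

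The low libraries differed in short RNAs, which bears on the histone, ribosomal protein and oxidative phosphorylation lists. Genes shorter than 1000 bases had a median log2 deviation from their group mean of 0.15 in low replicate 2 and -0.14 in low replicate 1. The mitochondrial 12S RNA, RNR1, was at 1092 CPM in low replicate 2 against 26.1 to 453 in the other libraries. Of 42 nuclear-encoded genes of oxidative phosphorylation 20 rose and none fell (median 0.24, camera adjusted p = 0.000181; adjusted p = 0.377 with an estimated correlation). ATP5F1A, of the ATP synthase, was at 289 ± 21.5 CPM against 207 ± 11.5 and COX5A at 22.4 ± 1.21 against 16.1 ± 1.63. Of 61 ribosomal protein genes 16 rose and 1, RPL5, fell, which was chosen after its value was seen (camera adjusted p = 0.0482; adjusted p = 0.745 with an estimated correlation). With library totals as the only scaling 27 rose and 0 fell. RPS28 rose by 0.64, with 25.5% of its exonic bases opposite another gene, and RPL7A by 0.37. That camera call was lost without high replicate 2 or 3 and without low replicate 1 or 3, at adjusted p = 0.106, 0.0760, 0.676 and 0.202. It was also lost with the correction for GC content and gene length (camera adjusted p = 0.208), with the stricter count filter (camera adjusted p = 0.0521) and with fry (adjusted p = 0.433). Without low replicate 2 the camera adjusted p was 2.53e-05 for ribosomal proteins, 1.6e-05 for oxidative phosphorylation and 3.81e-10 for histones. Adjusted over the list alone, the counts of both lists were the same.

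Cholesterol synthesis genes fell together in the high libraries: 20 of 22 were lower, SC5D was higher and PMVK was not called (median 1.54-fold lower, camera adjusted p = 1.97e-12; adjusted p = 0.147 with an estimated correlation). HMGCS1, which commits acetyl units to the pathway, was at 762 ± 59.0 CPM against 1465 ± 60.6 (log2 fold change -0.94, SE 0.05, edgeR adjusted p = 6.79e-18), MVD at 39.0 ± 3.44 against 83.9 ± 6.99 and LSS at 21.4 ± 2.79 against 41.5 ± 5.05. STARD4 also fell, though 70.7% of its exonic bases lie opposite other genes. SC5D was chosen after its value was seen. Of 18 p53 target and apoptosis genes 13 fell and none rose, 15 when adjusted over the list alone (median -0.39, camera adjusted p = 1.29e-05; adjusted p = 0.0657 with an estimated correlation). FAS was at 8.44 ± 0.896 CPM against 18.3 ± 1.46 and PHLDA3 at 24.2 ± 1.75 against 48.5 ± 0.265. Of 18 immediate early genes 10 fell and 2, NR4A2 and NR4A3, rose (camera adjusted p = 0.00121; adjusted p = 0.245 with an estimated correlation). JUN was at 105 ± 5.88 CPM against 292 ± 23.3 and DUSP1, a MAP kinase phosphatase, at 12.3 ± 1.74 against 47.0 ± 3.73. NR4A2 and NR4A3 were chosen after their values were seen, and the counts of the cholesterol and immediate early lists were the same when adjusted over the list alone.

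Of 20 heat shock and unfolded protein genes 10 fell and 4 rose, or 12 and 5 when adjusted over the list alone (camera adjusted p = 0.0224; adjusted p = 0.519 with an estimated correlation). The members that fell most, CHAC1, DDIT4, TRIB3 and ATF3, are targets of the integrated stress response, with ATF3 at 46.4 ± 0.621 CPM against 113 ± 7.70. The 4 that rose, HSPE1, HSPD1, HSPH1 and HSP90B1, are chaperones and were chosen after their values were seen. The camera call was lost without low replicate 2, at adjusted p = 0.103, and with the stricter count filter, at adjusted p = 0.0921.

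Of 19 BMP pathway genes 12 rose, 4 fell and 3 were not called (median 0.47, camera adjusted p = 0.000158; adjusted p = 0.1 with an estimated correlation). The direct targets ID1 and ID4 were at 36.1 ± 2.18 CPM against 10.2 ± 2.27 and 204 ± 8.01 against 58.6 ± 5.22, and SMAD9 at 89.8 ± 3.20 against 25.3 ± 1.62. The ligands moved apart: BMP7 differed by 2.18 and BMP4, at 61.2 ± 1.94 CPM against 126 ± 9.60, by -1.04. MSX1, BMP5 and BMP10 were the other lower members, chosen after their values were seen. Of 14 FGF pathway genes 7 rose, or 8 when adjusted over the list alone, and SPRY1, chosen after its value was seen, fell (camera adjusted p = 0.00118; adjusted p = 0.1 with an estimated correlation). FGF10, a ligand of the second heart field, was at 126 ± 6.25 CPM against 46.6 ± 1.30, and its feedback inhibitors SPRY4 and DUSP4 differed by 1.06 and 0.95. BMP7 shares 12.5% of its exonic bases with an antisense gene.

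Retinoic acid genes were called lower, with 7 of 13 lower and 3 higher (camera adjusted p = 0.0492; adjusted p = 0.2 with an estimated correlation). NR2F1, a retinoid-responsive receptor, was at 3.44 ± 0.371 CPM against 38.3 ± 1.40. Leaving out any library ended the list's call by camera, at adjusted p between 0.0569 and 0.228, as did the stricter count filter, at adjusted p = 0.107. WNT targets were not called as a list (5 of 15 higher, 4 lower, camera adjusted p = 0.992, median 0.04 with the camera direction lower). AXIN2, the WNT feedback gene, was at 13.5 ± 0.739 CPM against 30.0 ± 4.09 and LEF1 at 51.3 ± 3.10 against 108 ± 7.97, while DKK1, a secreted WNT inhibitor, was at 15.8 ± 2.43 against 5.83 ± 0.286. Secreted WNT inhibitors (3 of 8 higher, 2 lower, camera adjusted p = 0.637) and Notch genes (6 of 13 higher, 3 lower, camera adjusted p = 0.258) were not called by camera. LFNG and NRARP, of the Notch list, rose by 1.66 and 1.43. Adjusted over the list alone, the counts of these 4 lists were the same.

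Pluripotency genes were called higher, with 7 of 11 higher and TERF1, chosen after its value was seen, lower (median 0.58, camera adjusted p = 0.00444; adjusted p = 0.1 with an estimated correlation). SALL4 was at 115 ± 6.90 CPM against 58.9 ± 1.14 and TDGF1 at 38.3 ± 4.23 against 17.8 ± 0.769, and the counts were the same when adjusted over the list alone. POU5F1 had no count in any library, but that value cannot be read as absence. It has 6 further copies on other sequences of the annotation, and RPS18, DDX39B and TUBB, which every cell uses and which also have such copies, had no count on their own row either. Of protein-coding genes with over 3 such copies, 75.5% were at 0 in every library, against 8% of those without overlap. MESP1 and TBX6 had between 0 and 2 and between 1 and 16 counts per library and were not tested.

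Lists of other cell types that camera did not call held members moving both ways, as did the second heart field list, which is of the cardiac lineage. Among 14 endothelial genes 6 rose and 4 fell, 7 and 4 when adjusted over the list alone (camera adjusted p = 0.695), with FLT1 at 128 ± 2.26 CPM against 502 ± 21.7 and KDR higher. Its median of 0.47 was positive while fry gave a lower direction. Second heart field genes had 4 higher and 8 lower of 17, 5 and 8 when adjusted over the list alone (camera adjusted p = 0.138), and neural crest genes 2 higher and 4 lower of 7, 2 and 5 when adjusted over the list alone (camera adjusted p = 0.061, but 0.0266 with library totals as the only scaling), with SNAI2 at 50.4 ± 2.56 CPM against 232 ± 5.71. Amnion genes had 5 higher and 4 lower of 9 (camera adjusted p = 0.462), with GATA2 2.14 higher and HAND1 lower. Neural ectoderm genes had 3 higher and 1 lower of 6, 3 and 2 when adjusted over the list alone (camera adjusted p = 0.2), with OTX2 at 48.7 ± 1.23 CPM against 15.4 ± 0.739. Blood genes had 2 higher and 2 lower of 5 (camera adjusted p = 0.751), with LMO2 differing by 2.14 and HBE1, an embryonic globin, by -2.58, a median of -0.23 and a mean of 0.37. Presomitic genes had 2 higher and 2 lower of 5, 3 and 2 when adjusted over the list alone (camera adjusted p = 0.932). There MEOX1 had no count in the high libraries and 3.83 ± 0.343 CPM in the low, at least 53.5-fold lower against a floor of 3 counts over the group, and the median was 0.31 where fry gave a lower direction. Of the 4 primitive streak genes measured, too few to test as a list, APLNR rose by 0.60. Amnion and blood counts were the same when adjusted over the list alone.

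Of the metabolic and response lists, glycolysis and hypoxia (12 of 28 higher, 6 lower, camera adjusted p = 0.262), fatty acid oxidation (4 of 19 higher, 1 lower, camera adjusted p = 0.559), interferon response (2 of 7 higher, 2 lower, or 3 and 2 when adjusted over the list alone, camera adjusted p = 0.551) and nuclear-retained RNA (1 of 11 higher, 2 lower, camera adjusted p = 0.09) were not called by camera. Within glycolysis the glucose transporters moved apart, with SLC2A1 at 54.7 ± 5.90 CPM against 148 ± 7.50 and SLC2A3 at 1334 ± 53.8 against 538 ± 46.4. FABP3, a heart fatty acid binding protein with 16.2% of its exonic bases opposite another gene, differed by -1.52, and PPARGC1A, a regulator of mitochondrial biogenesis, by 0.85. Without low replicate 1 the nuclear-retained RNA list was called lower (camera adjusted p = 0.0129). IRF1 and NEAT1 differed by -1.13 and -0.50. The other counts were the same when adjusted over the list alone. The list of mitochondrially encoded messages had no member in the table.

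**Figure D4:**
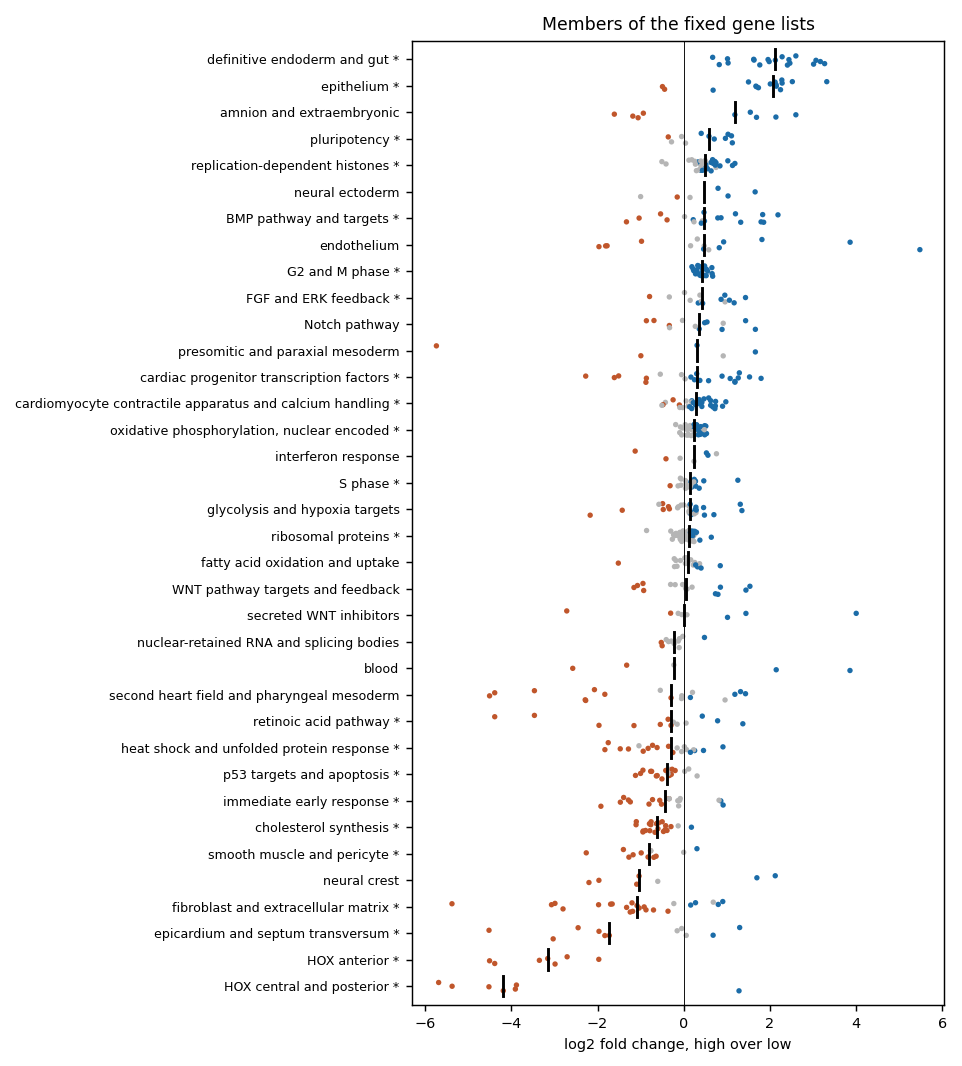
Log2 fold change (high over low) of each measured member of the 36 tested lists, blue where called higher, orange where called lower and grey where not called, with the list median as a black bar. Lists marked * passed the camera test with the preset correlation; genes with a group at 0 are drawn at the bound of 3 counts over the group.

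The 10 most abundant genes took 15.2 ± 0.540% of counts in high and 13.6 ± 1.28% in low libraries (exact permutation p = 0.2, both tails). Most of this was the mitochondrial ribosomal RNA RNR2, at a mean of 9.518% in high and 8.181% in low libraries. TTN, the giant sarcomere protein, took 1.26 ± 0.0865% against 0.757 ± 0.0498% and histones 0.153 ± 0.0081% against 0.108 ± 0.0198% (exact permutation p = 0.1 for each, the smallest that 3 against 3 allow). The TTN share was not among the measures planned. After adjustment over the 9 measures no p was below 0.3. Fold changes from the deposited TPM values correlated with those from counts at 0.9354 across genes on the log2(TPM + 1) scale, though genes are not independent replicates. The TPM values equal these counts over length, rescaled per library, so the agreement was fixed in advance and is no separate support.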

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

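The GC and length correction was the only alternative chosen after the results were seen. No gene called in the main fit was called in the opposite direction under any setting. The 7085 calls stayed between 5320 and 7290 under the other normalisations, filters, tests and log2 TPM fits, except 1991 with glmTreat against a 1.5-fold minimum and 4370 with limma on log2(TPM + 1) at a mean TPM of at least 1. The 1945 calls of at least 2-fold became 948 with the stricter filter, which tests fewer genes, 1088 with limma on log2(TPM + 1), where the added 1 shrinks folds of weak genes, and 1194 with the mean TPM limit. Leaving out each library gave 6158 to 7332 calls, 1963 to 2111 of at least 2-fold, and 18 to 21 lists. Of 22 lists, 1 stayed called when camera estimated the correlation per list. Some lists lost their call although the estimate was below the preset 0.01, among them pluripotency (-0.00775) and p53 targets (-0.0142). For these the loss is not an effect of correlation between genes. The FGF list (0.00196) lost its call as well, and the endoderm list (0.0088) went from camera adjusted p = 3.04e-16 to 0.0349. The setting thus weakens p-values apart from correlation, and a call lost under it does not show that correlation had made the call. The alternative fry called 32 lists, and the stricter filter left 15, with too few HOX genes to test either HOX list. Unlike camera, fry does not set a list against the other genes. With 41.2% of tested genes called, its calls answer another question and are easily reached. Library totals added the neural crest list (camera adjusted p = 0.0266), and fry added it among others. The correlation between folds from TPM and counts, 0.9354, was 0.9913 with a pseudocount of 0.1. A block on title replicate number gave 7159 calls, 1943 of at least 2-fold, and 24 lists, and TNNT2 passed. The lists added were neural crest (camera adjusted p = 0.0434) and nuclear-retained RNA (camera adjusted p = 0.0425). Deviations of libraries sharing a number correlated at 0.076, 0.087 and -0.052, and those of other pairs at -0.124 to 0.055. All are small, and 3 pairs cannot settle whether the numbers mark a pairing. Of 164 named genes tested, 118 kept their call under every alternative that tested them (the stricter filter tested 141), 46 changed under at least 1 (45 were weaker under glmTreat), and 0 reversed. Genes with few counts are limited by depth.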

Other observations

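The gene families, the independent lists and the test of the description prefix were chosen after the results of the report were seen. None of 16 families passed a Fisher exact test against all protein-coding genes, of which 22.8% were called higher and 22.4% lower. Collagens (16 of 41 lower, 10 higher, median -0.14) and integrins (9 of 17 lower, 5 higher) had a Fisher exact adjusted p = 0.118 each, though 0.0423 against all tested genes, non-coding ones included. ITGA8, a partner of nephronectin, was at 25.3 ± 0.787 CPM in the high and 103 ± 4.68 in the low libraries, ITGB3 at 7.53 ± 0.417 against 33.6 ± 0.816, and the collagen receptor ITGA2 at log2 fold change 2.13. SOX factors (7 of 13 higher, 3 lower) and forkhead factors (12 of 27 higher, 10 lower) had 0.118, ephrins and Eph receptors (9 of 19 higher, 5 lower) 0.148 and solute carriers (63 of 226 higher, 48 lower, median 0.04) 0.339 against protein-coding genes, where each had 0.0423 against all tested genes. SOX6, a factor of muscle and cartilage, was at 9.63 ± 0.492 CPM against 62.8 ± 4.35, and SOX21 at 18.3 ± 2.36 against 3.91 ± 0.329. FOXP1, expressed in outflow tract and myocardium, was at 134 ± 4.34 CPM against 68.1 ± 4.11. EPHA3 was at 0.241 ± 0.174 CPM against 5.78 ± 0.810 and EPHA1 at 7.35 ± 1.06 against 2.09 ± 0.360. All these genes were chosen after their values were seen.

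All 19 endoderm genes and 14 of 16 epithelial genes were higher in the high libraries, and the epithelial list was not called with an estimated correlation (camera adjusted p = 0.1). A bias of GC content or gene length does not account for this, since the median over both lists was 2.06 before and 2.04 after per-library trends were removed. A larger share of endoderm-type epithelial cells stays open beside higher expression in the progenitors themselves: of further markers outside the fixed lists 83.3% were called higher (25 of 30), which both would give, among them CGN at 134 ± 7.29 CPM against 36.3 ± 3.08 and VIL1 at 51.0 ± 1.56 against 11.6 ± 1.91. Not all followed: VTN, made by liver, had a log2 fold change of 0.07 and was not called, and KLF5 was called lower, at -0.67. The culture or vial set that the description prefix may mark cannot be told apart from efficiency, because 0 high libraries carry the prefix of the low libraries.

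In the high libraries all 7 anterior HOX genes, 6 of 7 central and posterior HOX genes and 6 of 11 epicardial genes were lower. None of these 3 lists stayed called with an estimated correlation (camera adjusted p = 0.0657, 0.0956 and 0.106). For the central and posterior HOX and the epicardial list the estimates, -0.0128 and -0.00891, were below the preset 0.01. Correlation between genes therefore does not account for the loss of those calls. The median over the 3 lists was -2.99 before and -2.98 after removal of trends on GC content and length, which argues against that bias. A larger share of epicardial-type cells in the low libraries stays open: of an independent list of epicardial and mesothelial genes 53.8% were called lower (7 of 13), between the limits set for and against. TGM2 was at 41.1 ± 0.532 CPM against 115 ± 5.78, but SLIT2 at 272 ± 6.58 against 272 ± 14.5, and C3 and EFEMP1 were called higher. A difference in the axial position of the mesoderm formed was not tested.

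In the high libraries 20 of 22 cholesterol synthesis genes and 13 of 18 p53 target genes were lower, calls of both lists that were lost with an estimated correlation (camera adjusted p = 0.147 and 0.0657). Removing trends on GC content and length left their median at -0.6, so that bias does not account for it. Lower activity of the sterol-regulated factors SREBP stays open, with 68.4% of their other targets called lower (13 of 19), such as LPIN1 at 57.9 ± 3.28 CPM against 127 ± 6.68. However, 3 were called higher, SREBF1, MID1IP1 and TM7SF2, and FASN was at 815 ± 42.0 against 809 ± 24.0. Cells that were more spread or less dense in the low libraries stay open too, with 65% of a YAP and TAZ target signature called lower (13 of 20), with CRIM1 at 264 ± 8.28 CPM against 536 ± 15.7. Of the same signature 2, MYOF and F3, were called higher, and CCN2 was at 510 ± 15.2 against 512 ± 13.4. Density at collection is not given in the sources used here.

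Of the 10 ways to divide the 6 libraries into 3 and 3, only the real one, 1 of 10, gave 7085 calls, and 1 of 10 gave 1945 of at least 2-fold, where no other gave any. For the lists it was also 1 of 10, with at most 11 lists under another division. These are too few divisions for a share under 0.05. Every other division also mixes high and low libraries, which puts the difference between them into the spread within groups. That the others called no gene was therefore set in advance and is no support. Part of the difference stays between the mixed groups, so the lists called there do not show a level without it.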
